A study of Homo sapiens with 38 samples.

How the data were processed

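Poly(A) RNA was sequenced from H9 cells, an established human embryonic stem cell line, before and during neural induction. The labels describe 38 paired-end libraries in 19 groups of 2. They comprise undifferentiated cells at day 0 and, at day 4 and again at day 8, 9 culture conditions. These were the WNT secretion inhibitor IWP2 at 2.0 µM, CT (the WNT activator, a name that the labels leave unexpanded) at 0.0, 0.4, 0.8, 1.0, 2.0, 3.0 and 4.0 µM, and CT at 4.0 µM together with retinoic acid (RA) at 1.0 µM. Groups are named here by day and condition, such as D4 CT0.4 or D8 CT4.0RA, and CT0.0 cells are called untreated. Libraries were run on 1 of 2 Illumina HiSeq models. The labels do not tie a library to a model, so a difference between instruments could not be examined.

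The values are TPM (transcript abundance corrected for length and scaled to a fixed total per library) per gene in the table the authors deposited. Per the submitters' processing notes, CASAVA 1.7, Salmon 0.8.2 and the hg38 build were used, and the order and settings of these steps are not given in the sources used here. The table holds 58219 genes by Ensembl identifier, of which 43661 were above 0 in at least 1 library. Of these identifiers, 57881 were matched without their version to GENCODE release 29 for gene type and position. TPM keeps no sequencing depth, so the number of reads behind each value is unknown and no counting interval can be given. Because of the fixed total, a gene class that takes more of the RNA lowers the values of all other genes. For this reason the share of TPM in 82 ribosomal protein genes and 37 mitochondrial genes was recorded for each group.

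Genes with at least 1 TPM in at least 2 of the 38 libraries were kept (28221 genes, 15533 of them protein-coding). On log2(TPM + 1), 19 group means were fitted over all libraries with limma (lmFit, contrasts.fit and eBayes with a trend), which leaves 19 residual degrees of freedom. All fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 within the contrast and its log2 fold change was at least 1 in size. Of the 23 contrasts, some compared days in untreated cells (day 4 with day 0, and day 8 with day 4). On each day IWP2 and each of 6 CT doses were compared with untreated cells, and CT4.0RA with CT4.0. A linear slope over the 7 CT doses was fitted on each day and called at 0.25 log2 units per µM. The last 3 contrasts are interactions, the day 8 effect less the day 4 effect of the CT slope, RA or IWP2. An F test over the 9 conditions was made on each day. SOX21 and WNT8B, the genes in the title of the series, were correlated over the 9 condition means per day with Pearson's r and Spearman's rho and exact two-sided permutation tests.

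Gene lists were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over 552 tests, and again with an estimated correlation. The 24 lists cover pluripotency, pan-neural progenitors, rostral forebrain, diencephalon, midbrain and isthmus, hindbrain, spinal cord, and dorsal and ventral neural tube. Others hold markers of neurons, neural crest, placode and surface ectoderm, mesoderm and endoderm. The remaining lists are SOX family B, WNT ligands, canonical WNT targets, secreted WNT antagonists, retinoic acid response, FGF and MAPK feedback, proliferation, stress and p53 targets, hypoxia and glycolysis, and cholesterol synthesis. They hold 414 symbols, repeats counted, 2 of which were not found in the table. Some genes stand in more than 1 list, so the tests of the lists are not independent of one another. Lists, contrasts, tests and the rule for named genes were fixed before the data were examined. The rule takes SOX21 and WNT8B, the 6 largest called changes in each direction per contrast whose replicates do not overlap, and, per list, the 4 largest called changes and the 2 genes of highest expression that did not pass. Clones without a gene name, antisense genes and pseudogenes that the rule took are not named, and a few other genes it took, with 1 test that rested on them, are not reported here. For slopes, named genes were limited to the title genes and the largest changes after the results were seen, because many list members did not change steadily with dose. The genes in the heat map, CDX1, CDX4, the levels printed for a gene in conditions other than those compared, and the genes named in the weighing of explanations were chosen after their values were seen.

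Replicates were compared before use. Of the 38 libraries, 33 had their highest correlation over log2(TPM + 1) with the other library of their own group, and r within groups ranged from 0.958 to 0.972. The exceptions were both D4 CT3.0 libraries, replicate 1 of D8 CT4.0 and both D8 CT0.0 libraries. For D8 CT0.0, r within the group was the lowest (0.9577), against 0.9584 and 0.9594 with D8 IWP2. D8 CT0.0 is the reference of every day 8 contrast with untreated cells. The libraries of no group held identical values. The procedure was tested on simulated data, with noise drawn independently for each gene around its mean over all libraries. Changes were added to the D8 CT4.0 libraries for 50 genes at each of 4 sizes among 28221, and D8 CT4.0 was compared with D8 CT0.0. The procedure called 0% of genes changed 1.5-fold, 32% at 2-fold, 94% at 4-fold and 100% at 8-fold, and 6 of 28001 unchanged genes. Changed genes were drawn only from those with a mean level well above that asked by the filter. These rates therefore do not cover low genes such as WNT8B. Alternatives set beforehand were another pseudocount (0.1), no filter on low values, TMM scaling, the replicate number as a block and only the libraries of the days compared. Also set beforehand were the rank of the dose, leaving out each dose, leaving out each library, and the estimated correlation. Alternatives added after the data were seen were rescaling each library by its protein-coding genes other than ribosomal protein and mitochondrial genes, protein-coding genes alone, and slopes over 0 to 2.0 µM. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.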

Results

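The series asked how graded WNT activation during neural induction of H9 cells shapes regional identity, with SOX21 and WNT8B in its title. Gene expression was measured in undifferentiated cells (D0 ESC) and in 9 conditions at day 4 and day 8, with 2 libraries in each of the 19 groups. The design text assigns rostral forebrain to IWP2, progressively more caudal brain regions to rising CT and spinal cord to CT4.0RA. The labels call the libraries biological replicates and do not say whether these were separate differentiations, so adjusted p-values measure the spread between those libraries. Values are mean TPM ± SD of 2 libraries, changes are log2 fold changes ± SE, and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless a list test is named. The F test over the 9 conditions passed for 13082 of 28221 genes at day 4 and for 16344 at day 8. Ribosomal protein genes held between 16.6% of TPM (D8 IWP2) and 36.8% (D8 CT4.0RA) by group.

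SOX21, a SOX family B transcription factor of neural progenitors, lies on chromosome 13 at 94709622 to 94712399 of hg38 on the minus strand (ENSG00000125285.5). WNT8B, a secreted WNT ligand, lies on chromosome 10 at 100463041 to 100483744 on the plus strand (ENSG00000075290.7). SOX21 stood at 8.01 ± 2.92 TPM in undifferentiated cells and 161 ± 7.0 in untreated cells at day 4 (log2 change 4.21 ± 0.26, adjusted p = 1.0e-11). At day 4 it lay between 82.9 and 106 TPM from CT0.4 to CT2.0. It was 14.6 ± 6.08 TPM at CT3.0 and 2.76 ± 1.31 at CT4.0, where it fell by 5.48 on the log2 scale (adjusted p = 2.4e-13). At day 8 its level did not follow the dose in order. It was 114 ± 20.4 TPM in untreated cells, 10.8 ± 4.05 at CT0.4, 51.1 ± 0.634 at CT0.8, 82.3 ± 6.64 at CT1.0 and 6.23 ± 1.68 at CT4.0. Against untreated cells SOX21 fell at CT0.4 (log2 change -3.32 ± 0.26, adjusted p = 1.8e-09) and at CT4.0 (-4.00 ± 0.26, adjusted p = 3.1e-11), and did not pass at CT1.0 (-0.46 ± 0.26). The fall at D8 CT0.8 (-1.14 ± 0.26) was under the threshold of 1 with TMM scaling (-0.99) and without replicate 1 of D8 CT0.0 (-0.96).

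WNT8B was a low gene at day 4, at 2.98 ± 0.290 TPM in untreated cells and at or under 0.558 TPM at every CT dose above 0.0. At day 8 it peaked at CT0.4 with 23.8 ± 11 TPM against 0.957 ± 0.904 in untreated cells (log2 change 3.67 ± 0.27, adjusted p = 9.6e-10). It also rose at CT0.8 (1.63 ± 0.27, adjusted p = 1.8e-04), to 4.82 ± 1.61 TPM. From CT2.0 upward at day 8 it was at or under 0.314 TPM, under the level asked of a tested gene. IWP2 left no called change in SOX21 (-0.34 ± 0.26 at day 4, -0.35 ± 0.26 at day 8) or WNT8B (-0.13 ± 0.27 and -0.72 ± 0.27). The day 8 value of WNT8B ranged from -1.21 to -0.23 when 1 library was left out, and passed without replicate 2 of D8 CT0.0 (adjusted p = 0.0469). The change of WNT8B from day 4 to day 8 in untreated cells was -1.10 ± 0.27 (adjusted p = 0.00587). It was -0.62 without replicate 2 of D8 CT0.0 and -1.03 without replicate 2 of D4 CT0.0, neither of which passed. With RA added to CT4.0, SOX21 rose at day 4 to 22.8 ± 0.253 TPM (2.70 ± 0.26, adjusted p = 4.8e-08), while the day 8 value was 0.47 ± 0.26 (adjusted p = 0.209). The difference between the days was -2.23 ± 0.36 (adjusted p = 1.6e-04). Per µM of CT, SOX21 fell at day 4 (slope -1.27 ± 0.05) and at day 8 (-0.71 ± 0.05), a difference of 0.56 ± 0.07 (adjusted p = 2.3e-06). WNT8B fell with dose at day 8 (-0.67 ± 0.05), a difference of -0.42 ± 0.08 from day 4 (adjusted p = 1.5e-04). Over doses of 0 to 2.0 µM alone, chosen after the data were seen, the SOX21 slope was -0.22 at day 4 and 0.22 at day 8, neither of which passed, and their difference of 0.44 lost its call (adjusted p = 0.108). The WNT8B slopes differed between the days by -0.17 over those doses and by -0.10 without the 0.4 µM dose, and neither passed.

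Across the 9 condition means no relation between SOX21 and WNT8B passed on either day in 4 exact two-sided permutation tests. At day 4 Pearson's r was 0.435 (p = 0.197, adjusted 0.425) and Spearman's rho was 0.467 (p = 0.213, adjusted 0.425). At day 8 r was -0.115 (p = 0.805, adjusted 0.805) and rho was 0.217 (p = 0.581, adjusted 0.775). In exact permutation tests without the 2 conditions farthest from the median of SOX21, r was 0.473 (p = 0.305) at day 4 and -0.504 (p = 0.211) at day 8. Within replicate 1 and replicate 2, r was 0.436 and 0.425 at day 4 and -0.103 and -0.0973 at day 8. Day 8 values changed sign between settings. There rho was -0.05 within replicate 1, 0.517 within replicate 2 and -0.214 without the 2 conditions, and r was 0.035 with a pseudocount of 0.1. WNT8B was under 1 TPM in most conditions on both days, so its order among them is uncertain and these tests cannot exclude a relation. Libraries could not be split by instrument.

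**Figure D1:**
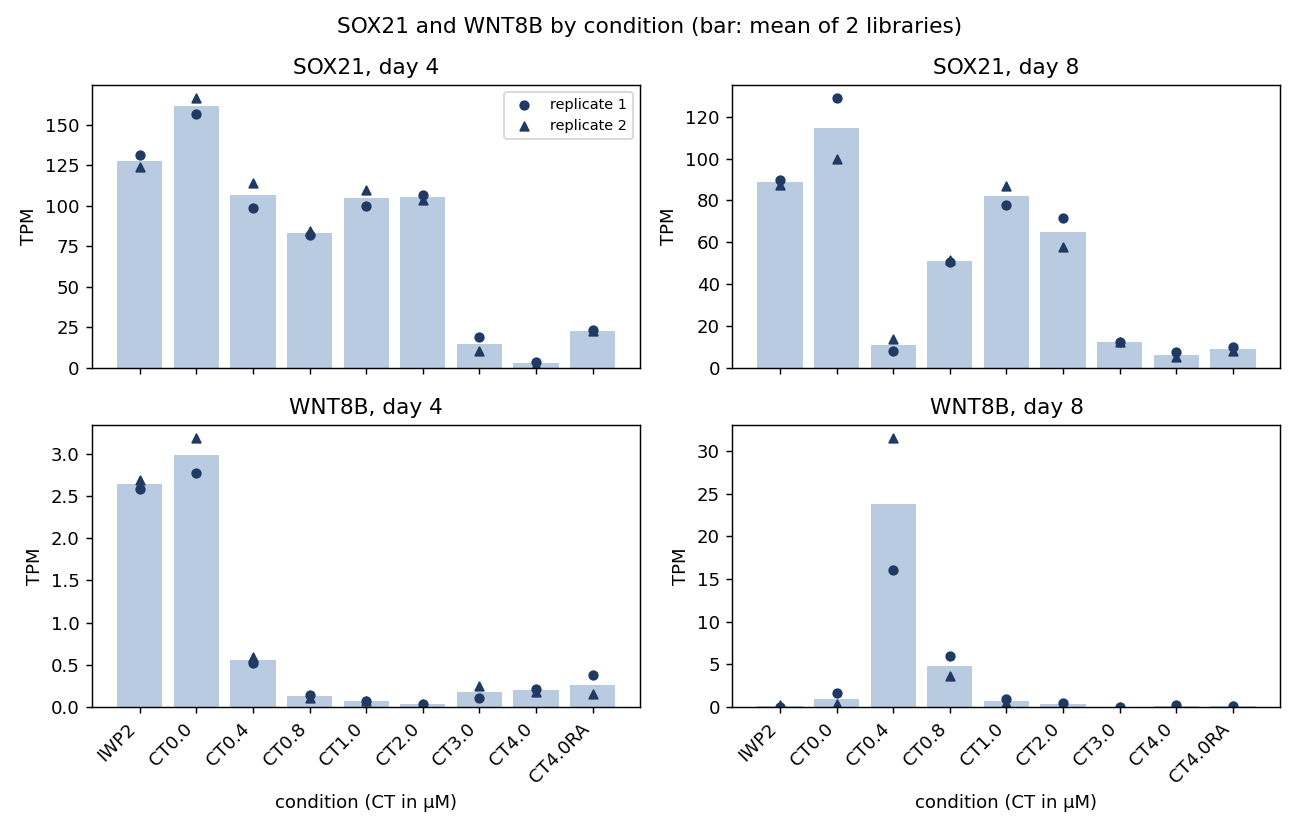
SOX21 (top) and WNT8B (bottom) in TPM for the 9 conditions at day 4 (left) and day 8 (right), with bars for the mean of 2 libraries and a point for each library. At day 8 CT0.4, SOX21 is at 10.8 TPM and WNT8B at 23.8 TPM, against 114 and 0.957 in untreated cells.

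The first 4 days of induction were followed in untreated cells. POU5F1, the core transcription factor of pluripotency, fell from 2457 ± 81.1 to 26.4 ± 8.40 TPM (log2 change -6.52 ± 0.31, adjusted p = 1.1e-13), and the NODAL co-receptor TDGF1 fell by 7.46 to 0.499 TPM. PAX6, an early neuroectoderm regulator, rose from 1.36 to 103 ± 4.81 TPM (5.46 ± 0.16, adjusted p = 5.2e-17). The eye-field and forebrain factors RAX (6.49 ± 0.21, to 112 ± 11.5 TPM), SIX3 (6.18 ± 0.20) and LHX2 (5.93 ± 0.35) rose as well. The imprinted gene DLK1 rose to 569 ± 56.3 TPM (7.74 ± 0.35). CDH1, the epithelial cadherin, fell from 96.0 to 0.385 TPM (-6.14 ± 0.27), and LDHA, a glycolytic enzyme, fell from 776 to 35.2 (-4.41 ± 0.21). Among the largest decreases were RARRES2 (-7.86 ± 0.38) and the stem cell transcript ESRG (-7.34 ± 0.16).

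Among the pluripotency genes (18 measured), 14 fell and 4 did not pass (camera adjusted p = 2.1e-15), with LIN28A at 0.34 ± 0.06 and DNMT3B at -0.97 ± 0.11 among those that did not. The pan-neural progenitor list had 23 measured genes, of which 17 rose and 6 did not pass (camera adjusted p = 6.7e-17). Of 18 measured rostral forebrain genes, 12 rose, 1 fell and 5 did not pass (camera adjusted p = 1.6e-09). Among the midbrain and isthmus genes (17 measured), 7 rose and 10 did not pass (camera adjusted p = 0.0174, and adjusted p = 0.122 with an estimated correlation), led by FGF8 (4.68 ± 0.27, to 41.6 TPM). The SOX family B list had 4 measured genes, of which 3 rose and 1 did not pass (camera adjusted p = 0.00772, and adjusted p = 0.181 with an estimated correlation). SOX2 rose by 1.21 ± 0.10 and SOX3 was at 0.00 ± 0.21. Of 15 measured placode and surface ectoderm genes, 1 rose, 7 fell and 7 did not pass (camera adjusted p = 0.00154). Among the mesoderm genes (8 measured), 4 fell and 4 did not pass (camera adjusted p = 0.0187, and adjusted p = 0.0604 with an estimated correlation). The endoderm list had 8 measured genes, of which 1 rose, 3 fell and 4 did not pass (camera adjusted p = 0.0671), with EPCAM at -4.66 ± 0.17. Of 16 measured hypoxia and glycolysis genes, 7 fell and 9 did not pass (camera adjusted p = 7.2e-06, and adjusted p = 0.0724 with an estimated correlation). Among the stress and p53 targets (16 measured), 2 fell and 14 did not pass (camera adjusted p = 5.5e-04). The neural crest list had 16 measured genes, of which 3 rose, 5 fell and 8 did not pass (camera adjusted p = 0.275). Of 10 measured secreted WNT antagonists, 2 rose, 2 fell and 6 did not pass (camera adjusted p = 0.874), the SFRP family member FRZB rising by 4.49 ± 0.24. No proliferation gene was called, while 9 were higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.124). The counts were the same when adjusted over the list alone. In all, 2120 genes were higher and 2608 lower at day 4 (1600 and 2916 with TMM scaling).

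From day 4 to day 8 forebrain genes changed in untreated cells. The forebrain factor FEZF2 rose from 2.35 to 36.1 ± 11.4 TPM (3.44 ± 0.36, adjusted p = 3.9e-07), and the cortical factor EMX2 rose as well (2.79 ± 0.24). The NOTCH effectors HES5 (6.47 ± 0.33, to 156 ± 0.707 TPM) and HES4 (4.70 ± 0.33) rose, whereas HES3, a marker of earlier neuroepithelium, fell from 83.4 to 1.15 TPM (-5.29 ± 0.33, adjusted p = 2.5e-10). HESX1 (-3.44 ± 0.30), PAX2 (-3.79 ± 0.32) and the remaining POU5F1 (-3.99 ± 0.31) fell. NPPB was listed at 0 at day 4 and was 58.1 ± 4.21 TPM at day 8. The pluripotency microRNA precursors MIR367 and MIR302A stood at 20.7 and 18.8 TPM at day 4 and were listed at 0 at day 8.

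Among the pluripotency genes (18 measured), 6 fell and 12 did not pass (camera adjusted p = 1.8e-07). The pan-neural progenitor list had 23 measured genes, of which 9 rose, 2 fell and 12 did not pass (camera adjusted p = 7.2e-06). Of 18 measured rostral forebrain genes, 6 rose, 5 fell and 7 did not pass (camera adjusted p = 0.930). Among the diencephalon genes (13 measured), 3 fell and 10 did not pass (camera adjusted p = 0.00127, and adjusted p = 0.106 with an estimated correlation). The neural crest list had 16 measured genes, of which 3 rose and 13 did not pass (camera adjusted p = 0.0352, and adjusted p = 0.145 with an estimated correlation), among them SOX9 (2.07 ± 0.16), which neural progenitors also express. Of 16 measured stress and p53 targets, 2 rose and 14 did not pass (camera adjusted p = 0.00250, and adjusted p = 0.0504 with an estimated correlation), namely ATF3 (1.30 ± 0.17) and CDKN1A (1.29 ± 0.23). No spinal cord gene was called, with 0 at an unadjusted p under 0.05 in either direction (camera adjusted p = 0.767). These counts were the same when adjusted over the list alone. In limma 1161 genes were higher and 470 lower at day 8, and 1063 were called in all when protein-coding genes alone were tested.

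IWP2, which blocks the secretion of WNT ligands, was compared with untreated cells to ask what endogenous WNT contributed. At day 4 NR2F1, a nuclear receptor of the developing neural tube, fell from 20.3 ± 2.54 to 4.72 TPM (-1.89 ± 0.25, adjusted p = 2.1e-04), with NR2F2 (-1.29 ± 0.21), OTX1 (-1.58 ± 0.26) and DBX1 (-2.15 ± 0.38). The eye-field gene SIX6 rose from 3.77 to 13.3 TPM (1.60 ± 0.15, adjusted p = 4.5e-06), and PAX2 rose (1.60 ± 0.32). The WNT target AXIN2 stood at 8.88 ± 0.716 against 13.7 ± 0.957 TPM (-0.57 ± 0.24, adjusted p = 0.342) and did not pass. Of the cholesterol synthesis list, STARD4, which carries sterols, fell by 1.00 (adjusted p = 3.3e-04), and the mevalonate pathway enzyme HMGCS1 was at 135 against 264 TPM (-0.97 ± 0.14).

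At day 8 NR2F1 (-1.88 ± 0.25) and NR2F2 (-1.42 ± 0.21) fell with IWP2. So did EMX2 (-2.55 ± 0.24), OTX1 (-2.56 ± 0.26) and FEZF2 (-2.22 ± 0.36), which are members of the rostral forebrain list. FGF8, a ligand of the anterior signalling centre, rose from 56.7 to 160.3 ± 24.2 TPM (1.48 ± 0.27, adjusted p = 0.00460), together with the ERK phosphatases DUSP6 (1.64 ± 0.29) and DUSP4 (1.12 ± 0.16) and with SIX3 (1.28 ± 0.20).

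At day 4, 1 of the 16 measured cholesterol synthesis genes fell and 15 did not pass (camera adjusted p = 2.4e-35, and adjusted p = 6.2e-04 with an estimated correlation), with a list median of -0.74. Among the pan-neural progenitor genes (23 measured), 3 fell and 20 did not pass (camera adjusted p = 5.1e-06). The diencephalon list had 13 measured genes, of which 2 fell and 11 did not pass (camera adjusted p = 3.3e-04, and adjusted p = 0.0734 with an estimated correlation). Of 19 measured canonical WNT targets, 1 fell and 18 did not pass (camera adjusted p = 0.00243, and adjusted p = 0.0717 with an estimated correlation). With p adjusted over the list alone, 3 diencephalon genes fell and the other counts here were the same. At day 8, 3 of the 18 measured FGF and MAPK feedback genes rose and 15 did not pass (camera adjusted p = 7.5e-10), 4 rising when adjusted over the list alone. Among the pan-neural progenitor genes (23 measured), 1 rose, 4 fell and 18 did not pass (camera adjusted p = 1.1e-07). The rostral forebrain list had 18 measured genes, of which 3 rose, 3 fell and 12 did not pass (camera adjusted p = 0.433). In limma no stress or cholesterol gene was called at day 8, while 7 and 12 were higher at an unadjusted p under 0.05 (camera adjusted p = 2.0e-05 for the former, camera adjusted p = 1.7e-08, and adjusted p = 0.0909 with an estimated correlation for the latter). The IWP2 effect on cholesterol synthesis differed between the days: it was higher at day 8 than at day 4 for 8 of 16 genes (camera adjusted p = 6.1e-35), with HMGCS1 at 1.52 ± 0.20 and MSMO1 at 1.24 ± 0.15. IWP2 gave 45 genes higher and 35 lower at day 4 (28 and 34 with TMM scaling) and 55 higher and 65 lower at day 8 (79 in all with a pseudocount of 0.1, and 78 with protein-coding genes alone). Leaving out 1 library gave 108 to 128 calls at day 4 and 136 to 194 at day 8. Several of the largest changes were small RNAs, which poly(A) libraries capture poorly. At day 4 there were 128 calls without replicate 1 and 126 without replicate 2 of D4 IWP2, and at day 8 there were 194 without replicate 2 of D8 CT0.0.

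Low CT doses were set against untreated cells to ask where diencephalic and midbrain genes appeared. At D4 CT0.4 the forebrain genes RAX (-6.27 ± 0.21, to 0.478 TPM), LHX2 (-5.70 ± 0.35) and SIX3 (-5.54 ± 0.20) fell, while OTX2, a forebrain and midbrain factor, stood at 421 ± 8.74 against 216 TPM. The midbrain and diencephalon gene DMBX1 rose to 62.1 ± 9.35 TPM (5.75 ± 0.23, adjusted p = 1.9e-13). The WNT target SP5 (5.58 ± 0.52), the sensory neuron factor POU4F1 (4.95 ± 0.30) and the WNT antagonist DKK1 (4.29 ± 0.30) rose as well. EN1, the midbrain and isthmus gene, was listed at 0 in untreated cells and was 6.75 ± 2.03 TPM at CT0.4 and 43.9 ± 8.11 at CT0.8. At CT0.8 WNT1 (4.67 ± 0.23), PAX8 (3.83 ± 0.32), the RA-degrading enzyme CYP26A1 (6.58 ± 0.33, to 159.5 ± 55.5 TPM) and the hindbrain gene HOXA2 (3.18 ± 0.19) rose, and SIX3 fell (-6.01 ± 0.20). At CT1.0 OTX2 fell to 8.19 ± 5.15 TPM (-4.68 ± 0.27, adjusted p = 2.8e-11), and HOXA2 reached 21.7 ± 4.42 TPM (4.43 ± 0.19).

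At D4 CT0.4, 6 of the 17 measured midbrain and isthmus genes rose, 3 fell and 8 did not pass (camera adjusted p = 1.1e-08). Of 19 measured canonical WNT targets, 6 rose, 2 fell and 11 did not pass (camera adjusted p = 5.6e-11). Among the rostral forebrain genes (18 measured), 2 rose, 7 fell and 9 did not pass (camera adjusted p = 0.00383, and adjusted p = 0.0668 with an estimated correlation). The diencephalon list had 13 measured genes, of which 5 rose, 2 fell and 6 did not pass (camera adjusted p = 4.6e-04, and adjusted p = 0.0802 with an estimated correlation). Of 18 measured FGF and MAPK feedback genes, 1 rose, 10 fell and 7 did not pass (camera adjusted p = 1.2e-07), DUSP6 reading 4.33 against 36.1 TPM. At D4 CT0.8, 10 of the 17 measured midbrain and isthmus genes rose, 3 fell and 4 did not pass (camera adjusted p = 4.2e-12). Among the rostral forebrain genes (18 measured), 9 fell and 9 did not pass (camera adjusted p = 5.4e-13). The retinoic acid response list had 19 measured genes, of which 5 rose and 14 did not pass (camera adjusted p = 8.1e-07). At D4 CT1.0, 1 of the 18 measured rostral forebrain genes rose, 10 fell and 7 did not pass (camera adjusted p = 2.6e-10). Of 19 measured hindbrain genes, 4 rose, 1 fell and 14 did not pass (camera adjusted p = 7.1e-05, and adjusted p = 0.0535 with an estimated correlation). Among the canonical WNT targets (19 measured), 4 fell and 15 did not pass at CT1.0 (camera adjusted p = 0.422), SP5 standing at 1.00 TPM. When adjusted over the list alone, 3 rostral forebrain genes rose at CT0.4, 6 retinoic acid response genes rose and 1 fell at CT0.8, and the other counts were the same. Calls were 186 higher and 443 lower at CT0.4 (241 and 249 with TMM scaling), 332 and 425 at CT0.8 (374 and 315) and 405 and 1068 at CT1.0 (556 and 545). The median log2 change of all genes was -0.10 at CT0.4 and -0.18 at CT1.0, against which these changes stand.

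At day 8, CT0.4 cells carried roof plate and dorsal midline genes at high levels. WNT1 rose from 0.0685 to 484 ± 90.0 TPM (8.82 ± 0.23, adjusted p = 4.8e-17). LMX1A, a roof plate and midbrain floor plate factor, rose to 224 ± 76.9 (7.60 ± 0.25, adjusted p = 1.5e-15), and the roof plate BMP ligand GDF7 to 65.4 ± 15.9 (5.93 ± 0.20). MSX1 (6.63 ± 0.37), PAX3 (5.28 ± 0.33), WNT10B (6.28 ± 0.28), WNT3A (5.87 ± 0.22) and WNT2B (5.64 ± 0.23) rose, as did the diencephalic gene BARHL1 (5.51 ± 0.24, to 52.4 ± 31.0 TPM). Replicates differed widely for some of these, as the SDs show and the SEs, pooled over all groups, do not. The WNT target AXIN2 rose to 295 ± 77.2 TPM (4.12 ± 0.24), and TTR, the choroid plexus transthyretin, was listed at 0 in untreated cells and was 27.2 ± 19.5 TPM. FZD5, a WNT receptor of the anterior neural plate, fell to 2.15 TPM (-5.91 ± 0.16, adjusted p = 4.8e-17). DLK1 (-7.34 ± 0.35), FGF8 (-4.54 ± 0.27) and SOX2 (-1.64 ± 0.10) fell, while OTX2 did not pass (0.59 ± 0.27).

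All 14 measured dorsal neural tube genes rose at D8 CT0.4 (camera adjusted p = 8.7e-34). The WNT ligand list had 14 measured genes, of which 8 rose, 2 fell and 4 did not pass (camera adjusted p = 6.1e-10). Of 13 measured diencephalon genes, 10 rose, 1 fell and 2 did not pass (camera adjusted p = 5.3e-09). Among the neuron genes (19 measured), 11 rose, 1 fell and 7 did not pass (camera adjusted p = 1.8e-11). The canonical WNT target list had 19 measured genes, of which 10 rose, 3 fell and 6 did not pass (camera adjusted p = 2.4e-08). Of 17 measured midbrain and isthmus genes, 6 rose, 2 fell and 9 did not pass (camera adjusted p = 5.0e-04). Among the rostral forebrain genes (18 measured), 1 rose, 9 fell and 8 did not pass (camera adjusted p = 1.4e-10). The FGF and MAPK feedback list had 18 measured genes, of which 7 fell and 11 did not pass (camera adjusted p = 1.3e-09). Of 4 measured SOX family B genes, 2 fell and 2 did not pass (camera adjusted p = 0.00220, and adjusted p = 0.127 with an estimated correlation). Among the neural crest genes (16 measured), 3 rose, 3 fell and 10 did not pass (camera adjusted p = 0.723), PAX3, TFAP2B and SNAI2 rising and SOX5 and NGFR among those falling. The placode and surface ectoderm list had 15 measured genes, of which 3 rose, 2 fell and 10 did not pass (camera adjusted p = 0.801). Of 8 measured mesoderm genes, 2 rose and 6 did not pass (camera adjusted p = 0.00865). The midbrain count of genes that fell and the mesoderm count of genes that rose were 3 when adjusted over the list alone, and the other counts were the same. At D8 CT0.8, 12 of the 14 measured dorsal neural tube genes rose and 2 did not pass (camera adjusted p = 1.3e-27). Among the midbrain and isthmus genes (17 measured), 10 rose, 3 fell and 4 did not pass (camera adjusted p = 4.0e-11). The rostral forebrain list had 18 measured genes, of which 13 fell and 5 did not pass (camera adjusted p = 4.8e-22). WNT1 was 135 ± 9.45 TPM and EN1 21.6 ± 0.155 at that dose. At D8 CT1.0, 11 of the 19 measured neuron genes rose and 8 did not pass (camera adjusted p = 2.7e-21). Of 18 measured rostral forebrain genes, 12 fell and 6 did not pass (camera adjusted p = 5.2e-24). Among the FGF and MAPK feedback genes (18 measured), 3 rose, 9 fell and 6 did not pass (camera adjusted p = 9.7e-08). The neurotrophin receptor NTRK2 (5.65 ± 0.29) and HES3 (5.79 ± 0.33) were among the largest increases at this dose. The ventral neural tube list had 11 measured genes, of which 6 rose, 1 fell and 4 did not pass (camera adjusted p = 8.7e-06, and adjusted p = 0.0802 with an estimated correlation), with 7 rising when adjusted over the list alone, GLI1 (2.58 ± 0.45) and SHH (1.86 ± 0.39) among them. SHH was low at CT1.0, at 3.02 ± 2.24 TPM, and NKX6-2 of the same list was 6.24 ± 3.90, so replicates differed widely. Calls were 1001 higher and 700 lower at CT0.4, 555 and 727 at CT0.8 (622 and 507 with TMM scaling, 836 in all with protein-coding genes alone) and 506 and 790 at CT1.0.

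CT2.0 was examined for hindbrain genes. HOXB1, which marks rhombomere 4, rose to 86.7 ± 26.1 TPM at day 4 (6.33 ± 0.16, adjusted p = 1.9e-17) and 98.7 ± 11.3 at day 8 (6.57 ± 0.16, adjusted p = 8.5e-18). EGR2, which marks rhombomeres 3 and 5, rose to 61.9 ± 11.3 TPM at day 4 (5.78 ± 0.26) and was 31.3 ± 9.95 at day 8. HOXB2 rose on both days (5.99 ± 0.14 and 6.36 ± 0.14), and the retinoid-binding protein gene CRABP1 reached 8913 ± 2151 TPM at day 4 (5.49 ± 0.45). OTX2 fell to 0.272 TPM at day 4 (-7.42 ± 0.27) and 0.709 at day 8 (-7.35 ± 0.27). The neuropeptide gene GALP rose at day 4 (6.48 ± 0.43).

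At D4 CT2.0, 11 of the 19 measured hindbrain genes rose and 8 did not pass (camera adjusted p = 8.0e-23). Of 19 measured retinoic acid response genes, 10 rose and 9 did not pass (camera adjusted p = 5.0e-10). Among the rostral forebrain genes (18 measured), 13 fell and 5 did not pass (camera adjusted p = 2.5e-17). The spinal cord list had 20 measured genes, of which 1 rose and 19 did not pass (camera adjusted p = 0.0217, and adjusted p = 0.494 with an estimated correlation), that gene being HOXB9 at 3.06 ± 3.69 TPM, which did not pass when adjusted over the list alone. At D8 CT2.0, 13 of the 19 measured hindbrain genes rose and 6 did not pass (camera adjusted p = 8.7e-27). Of 19 measured neuron genes, 12 rose and 7 did not pass (camera adjusted p = 1.4e-20). Among the retinoic acid response genes (19 measured), 10 rose and 9 did not pass (camera adjusted p = 1.1e-11). The proliferation list had 16 measured genes, of which 4 fell and 12 did not pass (camera adjusted p = 1.5e-17). Of 18 measured FGF and MAPK feedback genes, 10 fell and 8 did not pass (camera adjusted p = 7.4e-10), 11 falling when adjusted over the list alone. SPRY1, an inhibitor of FGF signalling, fell on both days (-4.48 ± 0.16 and -4.40 ± 0.16). At day 4, 1 retinoic acid response gene also fell when adjusted over the list alone, and the remaining counts were the same. Calls were 594 higher and 1087 lower at day 4 (754 and 728 with TMM scaling) and 582 and 1226 at day 8 (716 and 809), with a median change of all genes of -0.11 and -0.12.

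CT3.0 and CT4.0, the highest doses, were examined for trunk HOX genes and genes of axial progenitors. At D4 CT4.0 HOXB3 rose to 736 ± 60.8 TPM (9.37 ± 0.30, adjusted p = 3.7e-16), HOXB9 to 347 ± 10.1 (8.29 ± 0.51) and HOXC4 to 280.5 ± 37.8 (8.01 ± 0.23). HOXA7 was listed at 0 in untreated cells and was 281 ± 79.5 TPM. The neuromesodermal progenitor gene NKX1-2 (7.19 ± 0.23), FGF17 (7.81 ± 0.21, to 263 ± 35.0 TPM) and FGF8 (2.23 ± 0.27) rose, and the primitive streak gene T rose from 0.548 to 36.3 ± 7.05 TPM. The WNT targets SP5 (7.66 ± 0.52), NKD1 (3.83 ± 0.24) and AXIN2 (2.88 ± 0.24, adjusted p = 3.8e-09) rose. OTX2 fell to 0.232 TPM (-7.46 ± 0.27, adjusted p = 2.3e-15), PAX6 to 1.49 (-5.40 ± 0.16, adjusted p = 1.6e-16) and DLK1 to 1.51 (-7.82 ± 0.35). FEZF1, a forebrain factor at 436 ± 3.58 TPM in untreated cells, was listed at 0.

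Among the spinal cord genes (20 measured), 18 rose and 2 did not pass at D4 CT4.0 (camera adjusted p = 7.6e-38). The hindbrain list had 19 measured genes, of which 12 rose, 1 fell and 6 did not pass (camera adjusted p = 1.0e-20). Of 18 measured rostral forebrain genes, 14 fell and 4 did not pass (camera adjusted p = 3.7e-19). Among the pan-neural progenitor genes (23 measured), 1 rose, 14 fell and 8 did not pass (camera adjusted p = 8.8e-15). The SOX family B list had 4 measured genes, of which 3 fell and 1 did not pass (camera adjusted p = 2.0e-05). Of 19 measured canonical WNT targets, 10 rose, 4 fell and 5 did not pass (camera adjusted p = 1.3e-04). Among the FGF and MAPK feedback genes (18 measured), 7 rose, 3 fell and 8 did not pass (camera adjusted p = 2.4e-04, and adjusted p = 0.124 with an estimated correlation). The hypoxia and glycolysis list had 16 measured genes, of which 8 rose, 1 fell and 7 did not pass (camera adjusted p = 5.1e-09), with LDHA at 464 TPM (3.68 ± 0.21). Of 19 measured retinoic acid response genes, 7 rose, 4 fell and 8 did not pass (camera adjusted p = 0.00584), with the retinol transporter gene STRA6 at 4.42 ± 0.20. Among the diencephalon genes (13 measured), 1 rose, 5 fell and 7 did not pass (camera adjusted p = 0.00673, and adjusted p = 0.167 with an estimated correlation). The mesoderm list had 8 measured genes, of which 2 rose, 2 fell and 4 did not pass (camera adjusted p = 0.155). At D4 CT3.0, 17 of the 20 measured spinal cord genes rose and 3 did not pass (camera adjusted p = 3.4e-34), with HOXB9 at 499.8 ± 103 TPM. Counts adjusted over the list alone were the same. Calls were 810 higher and 1263 lower at CT3.0 (996 and 971 with TMM scaling) and 934 and 1407 at CT4.0 (1079 and 1067).

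At D8 CT4.0 HOXB3 stood at 657 ± 50.5 TPM (8.77 ± 0.30, adjusted p = 1.1e-15) and the caudal factor CDX2 at 131 ± 12.4 (6.97 ± 0.20). HOXB7 and T, both listed at 0 in untreated cells, were 258 ± 19.8 and 22.2 ± 1.32 TPM. FGF17 (7.76 ± 0.21), FGF8 (2.78 ± 0.27, to 395 TPM) and NKD1 (6.23 ± 0.24) rose. The progenitor genes DLK1 (-9.29 ± 0.35, adjusted p = 4.3e-15), HES5 (-6.88 ± 0.33), NR2F1 (-6.19 ± 0.25), PAX6 (-5.45 ± 0.16), SOX1 (-3.73 ± 0.23) and SOX2 (-1.47 ± 0.10, to 144 TPM) fell. The p53 target CDKN1A, a cell cycle inhibitor, rose from 9.95 to 139 TPM (3.68 ± 0.23, adjusted p = 2.2e-11), as did GDF15 (3.09 ± 0.20) and LDHA (3.62 ± 0.21), while MKI67 fell (-1.12 ± 0.11).

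Of 23 measured pan-neural progenitor genes, 20 fell and 3 did not pass at D8 CT4.0 (camera adjusted p = 1.5e-16). Among the rostral forebrain genes (18 measured), 15 fell and 3 did not pass (camera adjusted p = 5.9e-15). All 4 measured SOX family B genes fell (camera adjusted p = 1.3e-04, and adjusted p = 0.0642 with an estimated correlation). The spinal cord list had 20 measured genes, of which 17 rose and 3 did not pass (camera adjusted p = 8.8e-34). Of 19 measured hindbrain genes, 13 rose, 1 fell and 5 did not pass (camera adjusted p = 8.9e-22). Among the stress and p53 targets (16 measured), 7 rose and 9 did not pass (camera adjusted p = 6.6e-13). The hypoxia and glycolysis list had 16 measured genes, of which 11 rose, 2 fell and 3 did not pass (camera adjusted p = 4.2e-12). Of 16 measured proliferation genes, 4 fell and 12 did not pass (camera adjusted p = 1.4e-04, and adjusted p = 0.0980 with an estimated correlation). Among the canonical WNT targets (19 measured), 8 rose, 4 fell and 7 did not pass (camera adjusted p = 2.5e-04). The cholesterol synthesis list had 16 measured genes, of which 1 rose and 15 did not pass (camera adjusted p = 9.5e-10, and adjusted p = 0.0674 with an estimated correlation). By p adjusted over the list alone, 12 hypoxia and glycolysis genes rose and the other counts were the same. At D8 CT3.0, 5 of the 16 measured stress and p53 targets rose and 11 did not pass (camera adjusted p = 3.2e-12). Of 20 measured spinal cord genes, 15 rose and 5 did not pass (camera adjusted p = 6.3e-29). Among the pan-neural progenitor genes (23 measured), 20 fell and 3 did not pass (camera adjusted p = 2.8e-15). Calls were 877 higher and 3708 lower at CT3.0 and 889 and 3580 at CT4.0, against 1528 and 2018 and 1481 and 1977 with TMM scaling, and the median change of all genes was -0.28 and -0.27. Ribosomal protein genes held 29.4% of TPM at D8 CT3.0 and 28.4% at D8 CT4.0, against 19.0% in untreated cells. With protein-coding genes alone there were 3026 calls at CT3.0.

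**Figure D2:**
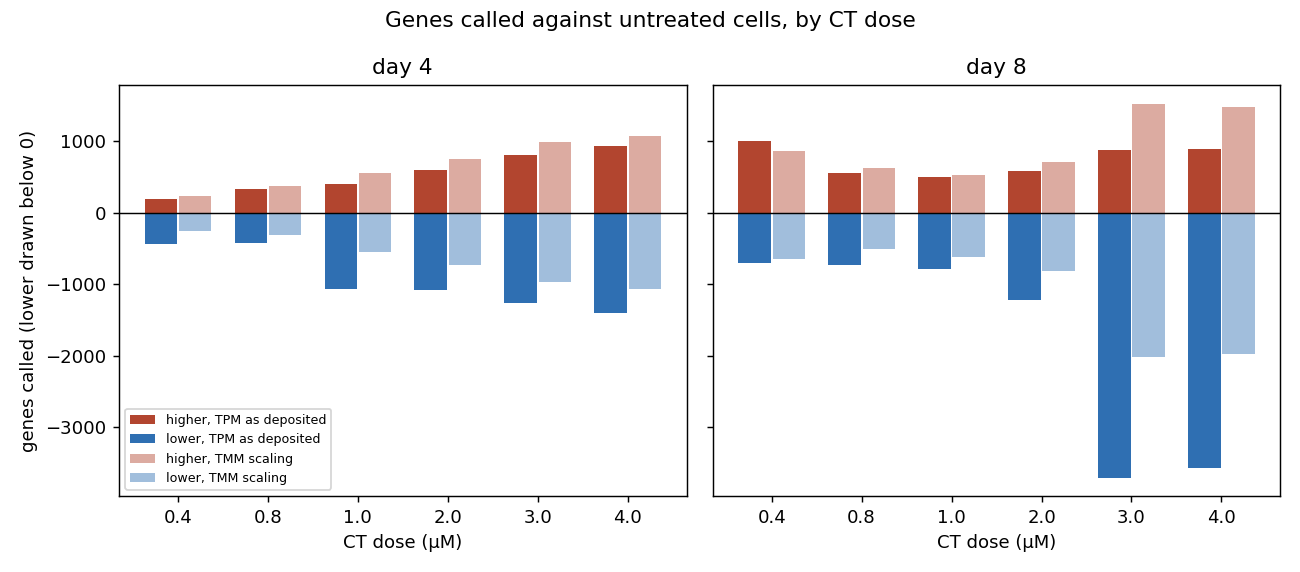
Number of genes called higher (red, above 0) and lower (blue, below 0) than in untreated cells at each CT dose in µM, at day 4 (left) and day 8 (right), for TPM as deposited (dark) and with TMM scaling (pale). At day 8 the lower calls number 3708 at 3.0 µM and 3580 at 4.0 µM with TPM as deposited, and 2018 and 1977 with TMM scaling.

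Over all 7 doses, among the steepest positive slopes were those of HOXB3 (2.86 ± 0.06 per µM at day 4 and 2.70 ± 0.06 at day 8) and HOXB9 (2.55 ± 0.10 and 2.30 ± 0.10), and among the steepest negative slopes those of OTX2 (-2.19 ± 0.05 and -2.21 ± 0.05). At day 4, 18 of the 20 measured spinal cord genes rose and 2 did not pass (camera adjusted p = 2.1e-35). The rostral forebrain list had 18 measured genes, of which 15 fell and 3 did not pass (camera adjusted p = 4.4e-20). Of 10 measured secreted WNT antagonists, 1 rose, 6 fell and 3 did not pass (camera adjusted p = 7.2e-06). At day 8, 1 of the 14 measured WNT ligand genes rose, 11 fell and 2 did not pass (camera adjusted p = 2.4e-04). Among the stress and p53 targets (16 measured), 7 rose and 9 did not pass (camera adjusted p = 2.3e-11). The pan-neural progenitor list had 23 measured genes, of which 20 fell and 3 did not pass (camera adjusted p = 1.6e-14). The slopes of 12 of 14 WNT ligand genes were lower at day 8 than at day 4 (camera adjusted p = 1.0e-07), those of 5 of 16 stress and p53 targets were higher (camera adjusted p = 6.2e-10), and those of 9 of 14 dorsal neural tube genes were lower (camera adjusted p = 1.2e-04, and adjusted p = 0.190 with an estimated correlation). Slope counts were the same when adjusted over the list alone. Over 0 to 2.0 µM alone, NR2F2 at day 8 had a slope of 0.47 against -1.64 ± 0.04 over all doses, and the stress and p53 targets tended downward at day 8 (adjusted p = 0.00165) and in the difference between days (adjusted p = 0.111). Slope calls were 1058 higher and 1102 lower at day 4 (1556 and 1698 with a pseudocount of 0.1, 1318 and 2861 over 0 to 2.0 µM at the same threshold per µM) and 1065 and 4640 at day 8 (1953 and 2535 with TMM scaling).

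**Figure D3:**
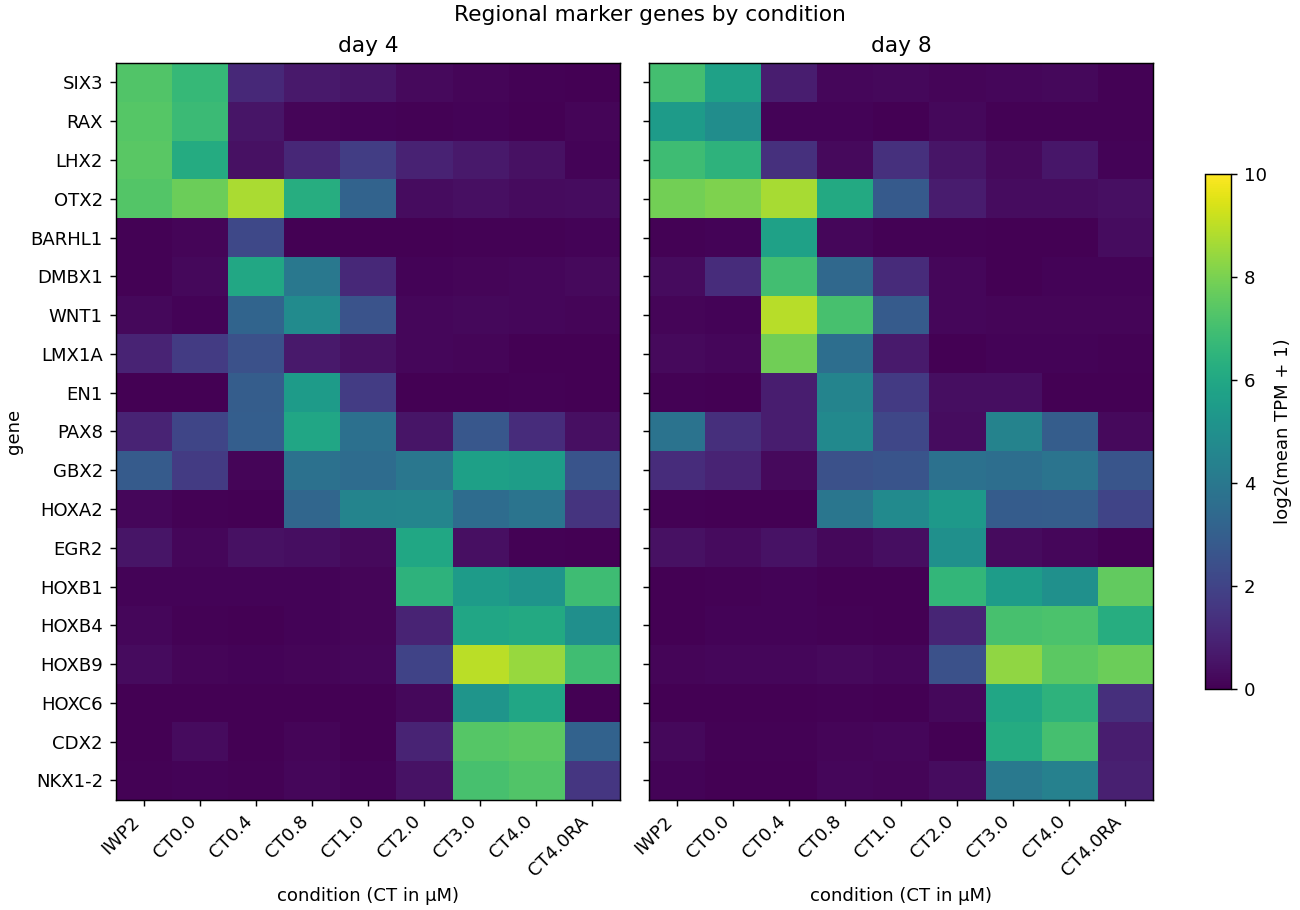
Heat map of log2(mean TPM + 1) for 19 regional marker genes in the 9 conditions at day 4 (left) and day 8 (right), each cell the mean of 2 libraries. From top to bottom the genes run from forebrain to trunk; at day 4 SIX3 is 102 TPM in CT0.0 and 1.23 TPM in CT0.4, EGR2 peaks at CT2.0 (61.9 TPM) and CDX2 at CT4.0 (179 TPM).

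CT4.0RA was compared with CT4.0 to ask what RA changed at the highest dose. At day 4 PAX6 rose from 1.49 to 168 ± 0.913 TPM (6.09 ± 0.16, adjusted p = 6.0e-17), and the direct RA targets CYP26A1 (7.01 ± 0.33) and RARB (4.11 ± 0.21) rose. So did HES5 (5.75 ± 0.33) and ONECUT1 (6.04 ± 0.36). FABP1, a fatty acid binding protein gene, was listed at 0 in CT4.0 and was 134 ± 1.99 TPM. FGF17 fell from 263 to 0.504 TPM (-7.45 ± 0.21, adjusted p = 7.9e-17), and HOXA7 (-7.58 ± 0.42), HOXC8 (-6.32 ± 0.26), NKX1-2 (-5.71 ± 0.23) and SP5 (-3.35 ± 0.52) fell. At day 8 PAX6 was 326 ± 0.824 TPM (7.02 ± 0.16, adjusted p = 2.9e-18), and the neuronal genes SNCG (7.09 ± 0.36), RELN (7.02 ± 0.25) and DCX (4.28 ± 0.18) rose. FGF8 fell from 395 to 0.872 TPM (-7.73 ± 0.27, adjusted p = 2.5e-15), with HOXA9 (-6.76 ± 0.43) and CDX2 (-6.26 ± 0.20). HOXB9 (0.30 ± 0.51) and HOXB3 (-0.29 ± 0.30) did not pass at day 8.

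The labels assign spinal cord to this condition. Against CT4.0, 1 of the 20 measured spinal cord genes rose, 17 fell and 2 did not pass at day 4 (camera adjusted p = 2.3e-17). At day 8, 1 of the 20 measured spinal cord genes rose, 14 fell and 5 did not pass (camera adjusted p = 1.7e-10, and adjusted p = 0.0642 with an estimated correlation). On both days the gene that rose was CDX1, a caudal gene that responds to RA (3.96 ± 0.28 and 5.47 ± 0.28). Those that fell at day 4 comprised trunk HOX genes, CDX2, CDX4 and NKX1-2, and NKX1-2 for one also marks axial progenitors. CT4.0RA was not compared with untreated cells, so a fall from CT4.0 does not show that spinal cord identity was absent. At day 8 HOXB9 stood at 217.7 TPM with CT4.0RA. Of the 19 list genes that passed the F test at day 8 and reached 1 TPM, 3 were highest with CT4.0RA and 14 with CT4.0. Whether the list is a fair measure of spinal cord identity was not tested. Of 19 measured retinoic acid response genes, 8 rose, 3 fell and 8 did not pass at day 4 (camera adjusted p = 1.7e-09). At day 8, 11 rose, 2 fell and 6 did not pass (camera adjusted p = 1.2e-08). Among the pan-neural progenitor genes (23 measured), 9 rose, 4 fell and 10 did not pass at day 4 (camera adjusted p = 1.6e-07). At day 8, 12 rose, 2 fell and 9 did not pass (camera adjusted p = 6.9e-08). The canonical WNT target list had 19 measured genes, of which 1 rose, 9 fell and 9 did not pass at day 4 (camera adjusted p = 0.00321, and adjusted p = 0.0769 with an estimated correlation). At day 8, 1 rose, 7 fell and 11 did not pass (camera adjusted p = 0.00198, and adjusted p = 0.0668 with an estimated correlation). Of 18 measured FGF and MAPK feedback genes, 1 rose, 11 fell and 6 did not pass at day 8 (camera adjusted p = 8.7e-12). Among the neuron genes (19 measured), 10 rose, 1 fell and 8 did not pass (camera adjusted p = 2.3e-07). The stress and p53 target list had 16 measured genes, of which 9 fell and 7 did not pass (camera adjusted p = 3.6e-12), with CDKN1A at -2.77 ± 0.23. Of 16 measured cholesterol synthesis genes, 8 fell and 8 did not pass (camera adjusted p = 4.1e-14). Among the proliferation genes (16 measured), 3 fell and 13 did not pass (camera adjusted p = 2.0e-09). All of these counts were the same adjusted over the list alone. Calls were 500 higher and 1148 lower at day 4 (687 and 728 with TMM scaling) and 1281 and 1223 at day 8 (1730 and 975 after rescaling without ribosomal protein and mitochondrial genes), with a median change of -0.18 at day 4.

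The RA effect itself differed between the days for 1570 genes that were higher and 441 lower at day 8 (1244 and 717 with TMM scaling), against a median of 0.13. The RA effect on STMN2, a neuronal growth gene, was 6.07 ± 0.28 higher at day 8 (adjusted p = 4.5e-12), most of it from a fall with RA at day 4 (-4.93 ± 0.20, from 61.5 to 1.05 TPM) against a rise of 1.14 ± 0.20 at day 8, to 42.0 TPM. For DUSP6 the difference was -4.53 ± 0.41 (adjusted p = 1.6e-07), from an RA effect of 0.12 ± 0.29 at day 4 and -4.40 ± 0.29 at day 8, with 259 ± 29.7 and 8.19 ± 2.43 TPM under RA. The effect of RA at day 8 was below that at day 4 for 10 of 18 FGF and MAPK feedback genes and above it for 1 (camera adjusted p = 2.5e-09), 11 and 2 when adjusted over the list alone. It was lower for 8 of 16 stress and p53 targets (camera adjusted p = 4.4e-13) and higher for 8 of 19 neuron genes and lower for 1 (camera adjusted p = 0.00119, and adjusted p = 0.0922 with an estimated correlation), 8 and 3 when adjusted over the list alone.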

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

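The tests of the ribosomal protein and mitochondrial share alone, of neural crest cells and of RNA from another condition were chosen after the results were seen, whereas the test of 1 common factor was set before its result was seen. The flagged results are differences between the days in the response to CT, RA or IWP2, each from the interaction term in limma, and the explanations were weighed with contrasts within day 8 as well.

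The CT slope differed between the days for 3931 genes. Among those with the largest differences, slopes were lower at day 8 for ZIC1, a dorsal neural tube gene (-1.56 per µM), for the annexins ANXA1 (-1.54) and ANXA2 (-1.30), for the natriuretic peptide NPPB (-1.42) and for CRIP1 (-1.32). ANXA1 was 23.5 TPM in untreated cells at day 8, 78.4 at CT0.4 and 0.0276 at CT3.0. Slopes were higher at day 8 for the small RNAs SCARNA18 (1.20), SNORA50A (1.10) and MIR6797 (1.04). The slope of SOX21 was 0.56 higher at day 8 and that of WNT8B 0.42 lower (-0.42). Over 0 to 2.0 µM alone both lost their calls (0.44, adjusted p = 0.108, and -0.17, adjusted p = 0.643), as did WNT8B without the 0.4 µM dose (-0.10, adjusted p = 0.417).

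The RA effect differed between the days for 2011 genes. It was higher at day 8 for SNCG (6.19), STMN2 (6.07, mostly from a fall with RA at day 4), Y_RNA (5.32), MIR1299 (5.28) and POMC (5.03), and lower for OLIG3 (-5.67), FABP1 (-5.02), DUSP6 (-4.53), FGF8 (-4.41) and SOX21 (-2.23). OLIG3, a dorsal progenitor factor, was 44.3 ± 1.00 TPM with RA at day 4 (0.775 at CT4.0) and 2.08 ± 0.219 at day 8 (5.12 at CT4.0), and POMC was 35.0 ± 1.65 TPM with RA at day 8. The IWP2 effect differed for 65 genes, 59 to 100 when 1 library was left out. It was higher at day 8 for PAX8 (3.49) and SNORA48 (2.42) and lower for U3 (-2.65) and SNORA32 (-2.58). MIR1299, Y_RNA, U3 and the small nucleolar RNAs are short transcripts that poly(A) libraries capture unevenly.

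More genes were called lower than higher at D8 CT3.0 and CT4.0, and the difference in slopes leaned the same way, with 568 slopes higher and 3363 lower at day 8. With TMM scaling 1046 slopes were higher and 1732 lower, and over doses of 0 to 2.0 µM 1063 and 1729. Over 0 to 2.0 µM the day 8 slope itself still had 1200 calls higher and 3735 lower, and the day 4 slope 1318 and 2861. At the same threshold per µM, slopes over 0 to 2.0 µM ask a smaller total change, so these counts do not compare with those over all doses. The direction of the day 8 lean, as distinct from its size, therefore does not rest on CT3.0 and CT4.0 only. At day 8 ribosomal protein genes held 19.0% of TPM in untreated cells, 29.4% at CT3.0 and 28.4% at CT4.0. The mitochondrial share went the other way, from 8.02% to 6.61% and 6.81%. An increase in the joint share of ribosomal protein and mitochondrial genes does not alone account for the excess of lower calls at D8 CT3.0 and CT4.0. After rescaling without them only 28.53% of calls at CT3.0 and 28.24% at CT4.0 were higher, under the 40% that this explanation required. A fall of all other genes by 1 common factor remains open: in 4 equal bins of mean expression the median changes differed by at least 0.284 log2 units, more than the 0.1 that a common factor allows and less than the 0.3 set as its exclusion. At CT3.0 these medians were -0.51, -0.63, -0.58 and -0.35 from the lowest to the highest bin. TMM scaling brought the calls that were higher from 19.13% to 43.09% at CT3.0 and from 19.89% to 42.83% at CT4.0, but it centres the median change at 0, so a move toward balance is built in and decides nothing here. A biological difference between the CT doses stays open and was not tested.

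The dorsal neural tube and WNT ligand genes at D8 CT0.4, which lower the day 8 slopes of both lists, were weighed against other sources of RNA. RNA of another condition is argued against, since 11 of the 14 dorsal genes, 78.57%, were higher in both CT0.4 libraries than in every other library of the series. Neural crest cells remain open: 0 of the 3 genes SOX10, FOXD3 and TFAP2A were called higher, but at 0.282, 0.313 and 0.318 TPM they lay under 1 TPM, where a small share of such cells could go unseen, so the bound set for this test was too weak to exclude them. PAX3, TFAP2B and SNAI2, which neural crest and dorsal neural tube share, rose, whereas SOX5 and NGFR fell. Markers of other cell types were also highest in these libraries among the day 8 conditions: TFAP2C at 49.1 TPM (0.77 in the next condition) and KRT19 at 77.4 (31.7) of surface ectoderm, and FOXF1 of mesoderm at 2.34 (0.045). As whole lists, placode and surface ectoderm did not pass (camera adjusted p = 0.801) and mesoderm tended upward (0.00865). Cells of these types stay open, as no share of them was estimated.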

How the results depend on the processing

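The alternatives of rescaling, protein-coding genes alone and doses of 0 to 2.0 µM were chosen after the data were seen, and the others beforehand. Over all alternatives, the main values were labelled unchanged in 1064 cases, moved in 12, stronger in 16, weaker in 8 and reversed in 1. Values of SOX21 and WNT8B were judged by whether a call, or the p of their correlation, crossed its threshold. Numbers of calls were labelled unchanged when the total differed by no more than 1.5-fold, whatever the split between higher and lower. Called list tests stayed in 3446 cases, lost significance in 290 and reversed in 14, and named genes stayed in 24688, gained a call in 202, lost it in 663 and reversed in 1. Slopes of list members other than the title genes and the largest changes are not in these counts, and their sign changes are given below. Under TMM scaling 224 of the 253 list calls held, 28 were lost and 1 reversed, that of proliferation at D4 CT0.4 (adjusted p = 0.998). With an estimated correlation 125 list tests passed against 253. Depth is unknown, so its effect on low genes could not be examined. Where a value moved the cause was not tested, except that testing fewer genes or fewer doses follows from the alternative itself.

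With a pseudocount of 0.1, IWP2 calls at day 8 were 79 against 120, day 4 slope calls 3254 against 2160, and WNT8B passed at D8 CT3.0 (-2.34), D8 CT4.0 (-1.85) and in the day 4 slope (-0.51). With protein-coding genes alone, calls were 1063 against 1631 for D8 against D4 untreated cells, 78 against 120 for IWP2 at day 8, 836 against 1282 at D8 CT0.8 and 3026 against 4585 at D8 CT3.0. SOX21 at D8 CT0.8 was -0.99 with TMM scaling. The WNT8B slope at day 4 passed on the rank of the dose (-0.33) and without the dose of 0.4 (-0.27), 0.8 (-0.29), 1.0 (-0.28), 3.0 (-0.26) or 4.0 µM (-0.41), and its difference between days was lost without 0.4 µM (-0.10).

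Over doses of 0 to 2.0 µM, day 4 slope calls were 4179 against 2160. The threshold per µM was the same, so the total change asked was smaller and the counts are not at a like threshold. The WNT8B slope at day 4 was -0.83 and its difference between days -0.17, the SOX21 slope -0.22 at day 4, 0.22 at day 8 (reversed) and 0.44 in their difference, which lost its call, and that of NR2F2 0.47 at day 8 (reversed). List tests that reversed there were, at day 4, SOX family B (adjusted p = 0.0674), FGF and MAPK feedback (5.6e-06), proliferation (1.5e-05), stress and p53 targets (0.0540) and cholesterol synthesis (5.8e-04). At day 8 these were SOX family B (0.0171), FGF and MAPK feedback (4.6e-07), stress and p53 targets (0.00165) and cholesterol synthesis (2.4e-11), and in the difference neurons (1.8e-07), stress and p53 targets (0.111), hypoxia and glycolysis (0.0658) and cholesterol synthesis (5.2e-07). Among list members whose slope was followed, the sign changed there for 24 of 120 at day 4, 41 of 121 at day 8 and 29 of 124 in the difference. Only sign changes with a call over all doses or over 0 to 2.0 µM were counted.

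Leaving out 1 library at a time, with the lone library of its group assumed to vary like the other groups, gave these ranges: IWP2 calls 108 to 128 at day 4 (80 with all libraries), 136 to 194 at day 8 (120) and 59 to 100 for the difference (65); WNT8B -1.59 to -0.62 for D8 against D4 untreated cells, -1.21 to -0.23 for IWP2 at day 8, -1.28 to -0.31 at D8 CT3.0, -1.18 to -0.20 at D8 CT4.0 and -0.26 to -0.24 for the day 4 slope; and SOX21 -1.32 to -0.96 at D8 CT0.8. Calls for IWP2 at day 4 were 128 without replicate 1 and 126 without replicate 2 of D4 IWP2. Without replicate 2 of D8 CT0.0, IWP2 calls were 194 at day 8 and 100 for the difference, and WNT8B was -0.62 against day 4, -1.21 with IWP2, -1.28 at CT3.0 and -1.18 at CT4.0, of which the last 3 gained a call and the first lost it. WNT8B against day 4 was -1.03 without replicate 2 of D4 CT0.0, and SOX21 at D8 CT0.8 was -0.96 without replicate 1 of D8 CT0.0. The WNT8B slope at day 4 passed without replicate 1 of D4 CT0.0 (-0.26), replicate 1 of D4 CT4.0 (-0.25) or replicate 2 of D4 CT3.0 (-0.26). With the replicate number as a block, all 253 list calls and 72 main values held, with 1 named gene gained and 4 lost. The replicate numbers come from labels that run through all groups, and no deviation shared by number was seen over all tested genes. Over 171 pairs of groups the correlation of deviations had a median of 0.00184 (-0.0427 to 0.0372), and 0 pairs were over 0.1. An effect limited to few genes could go unseen in this correlation.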

Other observations

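The test of another dose under the CT1.0 label was set before its result was seen. Condition peaks of the lists, given as counts of members that passed the F test and reached 1 TPM, differed between lists; a shift along the dose series was not tested. At day 4, 7 of 15 rostral forebrain genes were highest with IWP2, 5 of 8 diencephalon genes at CT0.4, 6 of 15 midbrain and isthmus genes at CT0.8 and 16 of 18 spinal cord genes at CT4.0. At day 8, 11 of 18 rostral forebrain genes were highest with IWP2, 7 of 13 diencephalon genes and 8 of 16 midbrain and isthmus genes at CT0.4, 13 of 14 dorsal neural tube genes at CT0.4 and 14 of 19 spinal cord genes at CT4.0. The midbrain and isthmus genes highest at CT0.4 include WNT1, LMX1A and PAX7, which the dorsal neural tube list also holds. EN1, EN2 and PAX8 were highest at CT0.8. Hindbrain genes had no common peak, with 5 of 19 each at CT2.0 and CT4.0 and 6 at CT4.0RA on day 4, and 6 of 19 at each of these on day 8. Pan-neural progenitor genes were most often highest at CT0.4 on day 8 (10 of 23), and proliferation genes with IWP2 (9 of 16). Peaks were taken from TPM as deposited. D8 IWP2 and D8 CT0.4 had the smallest ribosomal protein shares of all groups, 16.6% and 16.8%, which raises the TPM of other genes there. Peaks were not counted again after rescaling, so part of these counts may come from that share.

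HES3, which fell in untreated cells by day 8, stood at 118 ± 9.71 TPM at D8 CT1.0 and 199.8 ± 38.3 at D8 CT2.0 against 1.15 ± 0.0907 in untreated cells. PAX6 at day 8 was not ordered by dose, at 379 ± 37.6 TPM at CT0.4, 24.3 ± 0.917 at CT0.8, 174 ± 6.08 at CT2.0 and 5.79 ± 1.43 at CT3.0. 2 WNT target genes picked after their values were seen had a lower mean at D4 CT1.0 than at the doses beside it, which was not tested: SP5 was 23.3 ± 13.2 TPM at CT0.8, 1.00 ± 0.552 at CT1.0 and 38.1 ± 16.7 at CT2.0, and LEF1 was 31.9 ± 4.33, 13.7 ± 1.72 and 48.1 ± 4.66.

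FEZF2, a forebrain factor, was out of dose order at CT1.0. At day 8 it was 19.8 ± 5.05 TPM at CT1.0 against 2.69 ± 1.46 at CT0.8 and 0.601 ± 0.592 at CT2.0. At day 4 FEZF2 was highest with CT4.0RA (31.0 ± 3.49 TPM) and next at CT1.0 (15.3). The labels assign spinal cord to CT4.0RA, so FEZF2 alone does not mark forebrain identity here. Another dose under the CT1.0 label remains open: CT1.0 lay between CT0.8 and CT2.0 for 64.66% of 266 genes at day 4, against 53.01% for CT0.4 and 55.26% for CT3.0, and for 73.71% of 388 genes at day 8 against 51.55% and 44.85%. The smaller gap was 9.398 points, where 20 on both days would have excluded it. A response particular to this dose may also be the source and was not tested.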
